A study of Homo sapiens with 18 samples.

How the data were processed

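The series holds 18 RNA sequencing libraries of 293A cells, a human embryonic kidney line that grows attached to the dish, in 6 labelled groups of 3 replicates. The groups are 293A wt, USP7 KO, WT, MGA KO, USP7 KO#41 (the labels give 41 as part of the name) and USP7/MGA DKO, where KO is a knockout and DKO a double knockout. Per the labels, total RNA was taken with a spin column kit and libraries followed standard Illumina protocols. The read length, strand setting and dates are not given in the sources used here, and neither is the way each knockout was made.

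Each deposited table lists transcripts with a length, an effective length, a TPM value and an expected count, the estimated number of reads that Salmon assigns to a transcript. Per the submitters' processing notes the tools were FastQC, Salmon 0.14.1 and DESeq2 1.28.1, and the genome build was hg38. Salmon splits reads that match several transcripts between them, so genes with near-identical copies hold shares that depend on its model, and such genes are called uncertain here. Per the file headers the deposited TPM values are scaled within a library, and they were used only to describe levels. The deposited effective lengths (a length in bases, no unit of abundance) were used in 1 alternative. The tables hold 227201 transcripts of 60240 genes, 19649 of them with a coding transcript. Gene symbols and types come from the transcript names in the tables. The GENCODE release behind them is not given in the sources used here. Positions come from GENCODE 29 on GRCh38, in which 58064 genes (96.4%) had the same identifier.

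The expected counts were summed per gene and rounded to whole numbers before testing. Totals were 38594333 to 43368189 estimated reads in the 293A wt and USP7 KO libraries and 12119167 to 16525723 in the other 12. These 2 sets of libraries also differed in the share of mitochondrial reads (5.34 to 5.44% against 6.89 to 8.92%) and in the genes with at least 10 reads (20142 to 20718 against 15191 to 17100). The sets were fitted apart by the design, which did not rest on these differences. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom of 1.455 to 3.255 between replicates of the same group, so no replicate was a copy of another.

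The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) with TMM scaling, the default filter on low counts by group, and Benjamini-Hochberg adjustment over the genes tested. Genes with an adjusted p under 0.05 were called, and calls with a fold of 2 or more were counted beside them. USP7 KO and 293A wt were fitted as a pair of groups. The groups WT, MGA KO, USP7 KO#41 and USP7/MGA DKO shared a fit of 12 libraries, which gave their comparisons and the interaction (the double knockout minus both single effects). The difference of the USP7 knockout effects and WT against 293A wt used a fit of all 18 libraries. The labels do not pair the wild types with the knockouts. The pairing is an assumption, and the other wild type was tried as an alternative. The biological coefficient of variation was 2.70 to 2.78%. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

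Gene lists were tested with camera (limma 3.58.1), which compares the genes of a list with all other genes tested, with a preset correlation between genes of 0.01 and again with a correlation estimated from the data. The adjusted p-values cover 30 lists per comparison. The lists hold members of the PRC1.6 complex (the Polycomb repressor that MGA scaffolds), germline and meiosis genes that it is known to repress, X-linked cancer-testis genes, p53 targets, partners and substrates of USP7, the MAX and MYC network and MYC targets, genes of G1/S replication and G2/M mitosis, HOX genes, clustered protocadherins, cholesterol synthesis, ATF4 stress, ER chaperones, interferon-stimulated genes, Wnt targets, Notch and Hedgehog targets, hypoxia and glycolysis, oxidative phosphorylation, ribosomal proteins, proteasome and ubiquitin, the USP family, DNA repair, the core of PRC1 and PRC2, imprinted genes, extracellular matrix and adhesion, neuronal, epithelial, and blood and endothelial markers, and immediate early genes. Members called over all genes tested were counted, and also those called when adjusted over the list alone.

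Named genes followed a fixed rule. For each comparison these were USP7, MGA, PCGF6, L3MBTL2, E2F6 and MAX. Then came the 10 largest rises and the 10 largest falls among called coding genes with a mean TPM of 1 or more in at least 1 of the groups and no overlap between the replicates of the groups. Up to 4 members with the smallest adjusted p were added for each list described. For the interaction and the difference of effects, the 6 genes per direction with the smallest adjusted p were taken, and for overlaps up to 8 per direction. Sex-linked genes that could reveal the sex of a donor, antigen receptor segments and genes without a symbol were passed over. A few genes that the rule takes are not reported here, while counts and tests include them. The groups, comparisons, tests, lists, this rule and most alternatives were fixed before the data were examined.

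Where all libraries of a group had no reads for a gene, the fold is a lower bound set against a floor of 3 reads over the group. With 1 to 3 reads in a group, the ratio is given with its 95% counting interval. Both cover counting error only. Overlaps of calls were tested with Fisher's exact test, and correlations of log2 fold changes are across genes, which are not independent replicates. For the comparisons that share the WT libraries, 20 simulations of unchanged groups against shared controls gave the value without any effect, using the WT means for every group.

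The fits were tested on simulated data with known changes planted in a random set of genes, using the means, library sizes and spread of the real libraries. The shares below pool 5 random seeds, since a single seed moved a share by several points. For USP7 KO against 293A wt, 69% of genes changed by 1.5-fold, 82.5% changed by 2-fold and 98.2% changed by 4-fold were called in the right direction. For MGA KO against WT these shares were 74.6%, 83.9% and 96.7%. For the interaction they were 62.4%, 78.2% and 91.5%, and for the difference of the USP7 effects 66%, 77.8% and 92.4%. Unchanged genes were called in 0.091%, 0.072%, 0.076% and 0.064% of cases.

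The alternatives tried were RLE in place of TMM, no filter on low counts, an offset from effective lengths, DESeq2 1.42.0, only the groups compared or all 18 libraries in the fit, the other wild type as control, the replicate number as a block, each replicate left out in turn, fry and an estimated correlation for lists, and for correlations Pearson's r or genes with a mean count above 100. Chosen later, with results in hand, were 3 further pairs of comparisons for correlations, the removal of window medians along the chromosomes, an offset for GC content and the thinning of libraries to the smallest total. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Transcript usage is given only for USP7 and MGA.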

Results

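The study asked what the loss of USP7, a deubiquitinase known to act on MDM2 and p53, does in 293A cells, and how this relates to MGA, the scaffold of the Polycomb complex PRC1.6, which is known to hold germline genes silent. RNA was sequenced from 6 groups of 3 libraries: a wild type labelled 293A wt with a USP7 knockout, and a wild type labelled WT with an MGA knockout, a USP7 knockout labelled #41, and a double knockout. Gene values are log2 fold changes ± standard error with n = 3 libraries in each group, from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The p-values measure only the spread between these samples. List counts adjusted over the list alone are given where they differ from those over all genes.

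The targeted genes come first. USP7 transcripts were lower in every library labelled as a USP7 knockout but were not lost, with 97.2, 95.7 and 98.2 TPM in 293A wt and 39.5, 36.1 and 36.4 TPM in USP7 KO (-1.69 ± 0.03, adjusted p = 1.59e-16). WT held 178, 183 and 176 TPM, USP7 KO#41 34.2, 33.7 and 37 TPM (-2.64 ± 0.03, adjusted p = 6.27e-24), and the double knockout 45.4, 54.8 and 49 TPM. In MGA KO, USP7 stood at 172, 177 and 175 TPM (-0.06 ± 0.02, adjusted p = 0.0451). The call ended with RLE scaling (adjusted p = 0.067), DESeq2 (adjusted p = 0.145), an effective length offset (adjusted p = 0.402), the replicate number as a block (adjusted p = 0.0622), no count filter (adjusted p = 0.2) and only these groups in the fit (adjusted p = 0.092). It also ended without any single library of WT or MGA KO except WT replicate 2 (adjusted p = 0.0649 to 0.179). MGA was at 17.3, 14.8 and 15 TPM in WT and 12.2, 11.5 and 8.62 TPM in MGA KO (-0.73 ± 0.04, adjusted p = 1e-11), and at 8.34, 6.96 and 8.1 TPM in the double knockout (-1.32 ± 0.04 against WT, adjusted p = 2.41e-16). MGA transcripts rose in USP7 KO#41 to 25, 23.3 and 21.8 TPM (0.39 ± 0.04, adjusted p = 5.51e-09), and from 12.8, 12.1 and 13.1 TPM in 293A wt to 16.4, 16 and 15.5 TPM in USP7 KO (0.42 ± 0.04, adjusted p = 5.55e-08). The coding transcript USP7-202 averaged 47.5 TPM in 293A wt, 8.94 in USP7 KO, 108 in WT and 11.7 in USP7 KO#41. The transcript MGA-211 averaged 7.97 TPM in WT, 3.02 in MGA KO and 2.73 in the double knockout. A frameshift can leave the transcript in place, so these levels do not measure the protein.

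**Figure D1:**
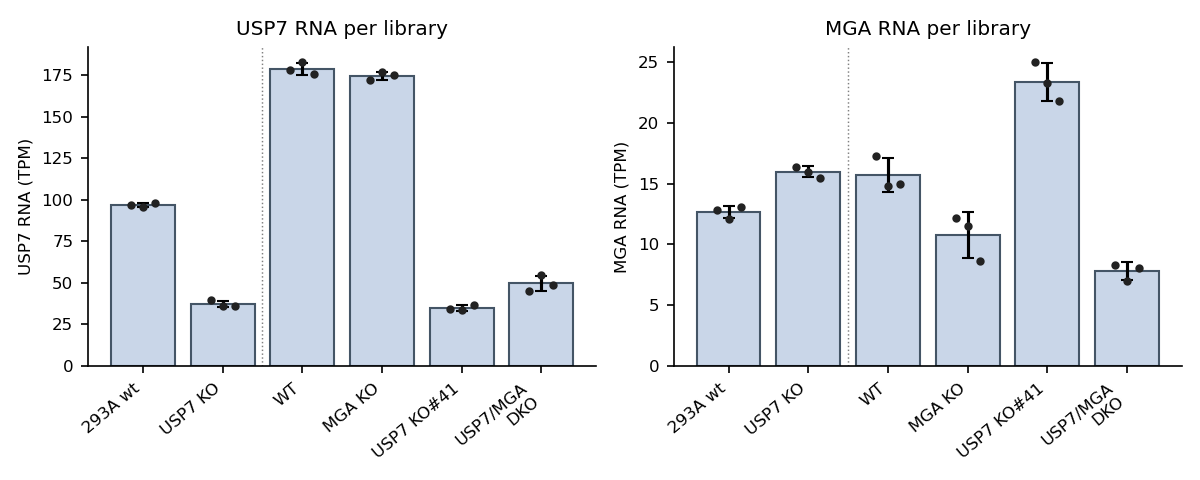
USP7 and MGA levels in TPM in each of the 18 libraries, with bars for the group mean and error bars for the standard deviation of 3 libraries. USP7 averaged 97.1 TPM in 293A wt and 37.4 in USP7 KO, and MGA averaged 15.7 TPM in WT and 10.8 in MGA KO.

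USP7 KO against 293A wt asks what the loss of USP7 changes. The largest rises were in genes that are nearly silent in the wild type. They include NELL1, a secreted protein of bone formation (716 reads against 1, ratio interval 126 to 27800) and the calcium channel subunit CACNG7 (6.97 ± 0.18). Next came the neuronal membrane protein PLPPR5 (6.8 ± 0.23), SOGA3 (6.64 ± 0.21), the metalloprotease ADAMTS12 (6.64 ± 0.28) and the growth factor carrier FGFBP1 (5.92 ± 0.12). Then came the transcription factor RFX6 (5.73 ± 0.28), TMEM229A (173 reads against 3, ratio interval 19 to 277) and the acetylcholine receptor subunit CHRNA4 (5.62 ± 0.27). The largest falls were in IRF5, a transcription factor of the interferon response (at least 465-fold lower), FOXL2, a transcription factor of the ovary (at least 115-fold lower), interferon beta, IFNB1 (at least 39.1-fold lower), and MAGEB2 (-8.11 ± 0.15). MAGEA2B, MAGEA2, CSAG3 and F8A3 (at least 263, 156, 145 and 101 times lower) also fell. So did MAGEA6 (1 read against 1331, ratio interval 1.86e-05 to 0.00411) and MAGEA3 (2 reads against 688, ratio interval 0.000345 to 0.0103). All have near-copies, so the share of each is uncertain. Of the partners of MGA, L3MBTL2 (0.26 ± 0.04), E2F6 (0.54 ± 0.03) and MAX (0.19 ± 0.04) rose, MAX not with an effective length offset (adjusted p = 0.162). PCGF6 did not pass (-0.04 ± 0.04, adjusted p = 0.488).

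Among p53 targets 2 of 34 rose and 31 fell, median -0.48, adjusted p = 5.16e-09 and adjusted p = 0.117 with an estimated correlation. Falls were in BAX, which promotes cell death (-0.96 ± 0.03), MDM2, which degrades p53 (-0.9 ± 0.02), TP53INP1 (-1.51 ± 0.04) and ZMAT3 (-1.19 ± 0.03). Among MYC targets 32 of 40 rose and 3 fell, median 0.31, adjusted p = 3.8e-06 and adjusted p = 0.123 with an estimated correlation. They include SRM, the spermidine synthase (1.19 ± 0.04), ODC1, which starts polyamine synthesis (0.74 ± 0.02), and the nucleolar protein NOP56 (0.7 ± 0.02). For X-linked cancer-testis genes 0 of 11 rose and 9 fell, median -6.09, adjusted p = 7.17e-05 and adjusted p = 0.117 with an estimated correlation. MAGEA10 was among the falls (-3.15 ± 0.26), and with bounds for genes without reads the median was -4.83. Neuronal markers, some of which this cell line expresses, moved too: 14 of 17 rose and 2 fell, median 1.14, adjusted p = 0.000131 and adjusted p = 0.13 with an estimated correlation. Rises were in tubulin TUBB3 (2.29 ± 0.04) and in the filament genes NEFM (3.86 ± 0.1) and INA (3.49 ± 0.1). Of the G1/S replication genes 4 of 38 rose and 27 fell (5 and 28 adjusted over the list alone), median -0.19, adjusted p = 0.000139 and adjusted p = 0.123 with an estimated correlation. They include MCM2 of the replicative helicase (-0.58 ± 0.02) and RFC4 of the clamp loader (-0.66 ± 0.03), while E2F2 rose (0.71 ± 0.04). Of the DNA repair genes 4 of 49 rose and 32 fell, median -0.18, adjusted p = 0.000261 and adjusted p = 0.117 with an estimated correlation. They include the ligase LIG1 (-0.74 ± 0.03), the nuclease ERCC5 (-0.97 ± 0.04) and the damage kinase ATR (-0.59 ± 0.04). For ER chaperones 15 of 21 rose and 2 fell, median 0.25, adjusted p = 0.00195 and adjusted p = 0.194 with an estimated correlation. Of these, HSPA5 (0.88 ± 0.02), PDIA4 (0.66 ± 0.02), CRELD2 (0.93 ± 0.03) and HYOU1 (0.6 ± 0.02) were higher.

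Of the Wnt targets 15 of 20 rose and 3 fell (15 and 4 adjusted over the list alone), median 0.49, adjusted p = 0.00401 and adjusted p = 0.123 with an estimated correlation. Rises were in TBX3 (1 ± 0.03), LEF1 (0.78 ± 0.04) and RNF43 (0.81 ± 0.05). Among immediate early genes 17 of 30 rose and 6 fell, median 0.21, adjusted p = 0.0252 and adjusted p = 0.194 with an estimated correlation. They include EGR2 (3.16 ± 0.13), ETV4 (0.96 ± 0.06) and DUSP1 (0.73 ± 0.03). For ATF4 targets 21 of 34 rose and 10 fell, median 0.26, adjusted p = 0.0491 and adjusted p = 0.385 with an estimated correlation. Of these, the cystine transporter SLC7A11 (1.51 ± 0.05) and TRIB3 (0.79 ± 0.04) were higher. The ATF4 list lost its call without 293A wt replicate 1, 2 or 3 (adjusted p = 0.0592 to 0.063). For proteasome and ubiquitin genes 23 of 35 rose and 4 fell (24 and 4 adjusted over the list alone), median 0.14, adjusted p = 0.00606 and adjusted p = 0.516 with an estimated correlation. For G2/M genes 24 of 36 rose and 7 fell, median 0.14, adjusted p = 0.00935 and adjusted p = 0.6 with an estimated correlation. For ribosomal proteins 20 of 75 rose and 48 fell, median -0.16, adjusted p = 0.00309 and adjusted p = 0.743 with an estimated correlation. Other lists did not pass. Of the interferon-stimulated genes 17 of 45 rose and 19 fell, median -0.11, adjusted p = 0.771. The antigen presenter HLA-B rose (1.5 ± 0.03), while the antiviral IFIT2 (-4.39 ± 0.08) and IFIT1 (-3.17 ± 0.06) fell, but rose with the other wild type as control (3.01 and 1.57). Of the germline genes 9 of 31 rose and 7 fell, median 0.05, adjusted p = 0.825. Of the PRC1.6 members 6 of 18 rose and 8 fell, median -0.04, adjusted p = 0.825. In all, 12683 of 20650 tested genes were called, 6518 higher and 6165 lower, and 2351 of them by 2-fold or more (1309 higher, 1042 lower). None of the 13 called lists held with an estimated correlation.

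USP7 KO#41 against WT asks the same of another USP7 knockout group with its own libraries. The largest rises were again in silent genes and include SOGA3, NELL1 and the keratin KRT75 (at least 330, 101 and 52.2 times higher). Others were ADAMTS12 (1037 reads against 2, ratio interval 136 to 4070), the ephrin receptor EPHA6 (at least 42.7-fold higher) and the endothelial transcription factor ERG (at least 37.7-fold higher). After these came PLPPR5, the Notch regulator DTX1 and the lectin CLEC2B (at least 37, 34.2 and 33.5 times higher). The largest falls were in KRBOX1, IRF5, FOXL2 and the retinol carrier RBP4 (at least 47.4, 41.8, 33 and 14 times lower). Of these, only KRBOX1 also had 0 reads in the double knockout. Beside these stood PARP12 (2 reads against 160, ratio interval 0.00142 to 0.0436), ZNF280D (-5.7 ± 0.25) and the collagen COL2A1 (-5.44 ± 0.13). F8A1 (at least 33-fold lower), F8A3 (1 read against 69, ratio interval 0.000343 to 0.0792) and the protocadherin PCDHGB5 (-7.84 ± 0.31) have near-copies or share exons, so their falls are uncertain. Of the partners of MGA, PCGF6 (-0.68 ± 0.05) and L3MBTL2 (-0.5 ± 0.05) fell and E2F6 rose (0.42 ± 0.05). MAX was at -0.14 ± 0.05 (adjusted p = 0.0118). This call ended without WT replicate 3 (-0.10, adjusted p = 0.0812), with DESeq2 (adjusted p = 0.137) and with an effective length offset (adjusted p = 0.918). It also ended without the count filter (adjusted p = 0.064) and with only these groups in the fit (adjusted p = 0.103).

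Of the G1/S replication genes 1 of 38 rose and 37 fell, median -0.46, adjusted p = 7.88e-11. They include UHRF1, which copies DNA methylation (-0.87 ± 0.03), the polymerase POLA1 (-0.73 ± 0.03) and MCM7 (-0.76 ± 0.03). Interferon-stimulated genes moved the other way: 33 of 43 rose and 2 fell, median 0.84, adjusted p = 5.08e-08. They include the DNA sensor IFI16 (5.17 ± 0.13), the virus tether BST2 (3.3 ± 0.1), HLA-B (1.55 ± 0.05) and OAS3 (1.32 ± 0.04). Of the DNA repair genes 1 of 49 rose and 40 fell, median -0.32, adjusted p = 7.02e-08. Of these, LIG1 (-1.1 ± 0.04) and the kinase PRKDC (-0.53 ± 0.02) were lower. For neuronal markers 14 of 17 rose and 0 fell, median 1.2, adjusted p = 2.15e-06. Of these, INA (3.33 ± 0.2), the adhesion gene L1CAM (1.2 ± 0.08), NEFL (1.14 ± 0.03) and NEFM (552 reads against 3, ratio interval 59.5 to 850) were higher. These lists, 4 of 17 called, held with an estimated correlation (adjusted p = 0.0011 to 0.0113).

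Of the MYC targets 0 of 40 rose and 37 fell, median -0.34, adjusted p = 4.3e-08 and adjusted p = 0.0782 with an estimated correlation. Of these, MCM4 (-0.66 ± 0.03) and the nucleolar NOLC1 (-0.52 ± 0.03) were lower. For ER chaperones 15 of 21 rose and 1 fell, median 0.38, adjusted p = 4.42e-05 and adjusted p = 0.0504 with an estimated correlation. They include HSPA5 (0.84 ± 0.03), HYOU1 (0.76 ± 0.03) and PDIA4 (0.71 ± 0.03). Of the blood and endothelial markers, genes of other cell types, 8 of 21 were tested. Of these 7 rose and 0 fell, median 1.71, adjusted p = 0.00487 and adjusted p = 0.0725 with an estimated correlation. They include the receptor KDR (2.88 ± 0.41), the clotting protein VWF (2.16 ± 0.2), the macrophage gene CD68 (1.81 ± 0.15) and CD34 (1.61 ± 0.25). Of the PRC1.6 members 3 of 18 rose and 12 fell, median -0.24, adjusted p = 0.0151 and adjusted p = 0.0782 with an estimated correlation. They include TFDP1 (-1.23 ± 0.03), WDR5 (-0.75 ± 0.03), the methyltransferase EHMT1 (-0.64 ± 0.03) and CBX3 (-0.54 ± 0.03). Window medians here were -0.57 for TFDP1, -0.24 for CBX3, -0.39 for PCGF6 and -0.11 for L3MBTL2. Of the PRC1 and PRC2 core 5 of 34 rose and 18 fell, median -0.15, adjusted p = 0.0309 and adjusted p = 0.0782 with an estimated correlation. They include BCOR (-0.91 ± 0.02) and RBBP7 (-0.96 ± 0.03). Of the partners and substrates of USP7 4 of 29 rose and 18 fell, median -0.18, adjusted p = 0.0105 and adjusted p = 0.111 with an estimated correlation. Of these, GMPS (-0.65 ± 0.03) and the methyltransferase DNMT1 (-0.52 ± 0.03) were lower, and here the mean was 0.04 while the median and the test pointed down. Of the p53 targets 7 of 34 rose and 20 fell (7 and 22 adjusted over the list alone), median -0.24, adjusted p = 0.0346 and adjusted p = 0.283 with an estimated correlation. ZMAT3 (-0.78 ± 0.05) fell, and GADD45A (0.78 ± 0.06) and PMAIP1 (0.57 ± 0.03) rose. Of the Wnt targets 10 of 20 rose and 3 fell, median 0.34, adjusted p = 0.0252 and adjusted p = 0.111 with an estimated correlation, RNF43 among the rises (2.28 ± 0.07).

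For the proteasome 1 of 35 rose and 23 fell, median -0.18, adjusted p = 0.000727 and adjusted p = 0.111 with an estimated correlation. For G2/M genes 2 of 36 rose and 24 fell (3 and 25 adjusted over the list alone), median -0.15, adjusted p = 0.00311 and adjusted p = 0.283 with an estimated correlation. For oxidative phosphorylation 3 of 44 rose and 25 fell, median -0.13, adjusted p = 0.00487 and adjusted p = 0.271 with an estimated correlation. For the USP family 5 of 43 rose and 25 fell (6 and 25 adjusted over the list alone), median -0.14, adjusted p = 0.00749 and adjusted p = 0.111 with an estimated correlation. For cholesterol synthesis 4 of 24 rose and 12 fell, median -0.16, adjusted p = 0.0346 and adjusted p = 0.196 with an estimated correlation. Germline genes did not pass as a list: 13 of 24 rose and 3 fell (14 and 5 adjusted over the list alone), median 0.53, adjusted p = 0.0622. MEIOC, needed for meiosis (1.64 ± 0.07), and SYCE2 of the synaptonemal complex (2.37 ± 0.23) rose, and TAF7L (-2.18 ± 0.1) and MNS1 (-2.45 ± 0.12) fell. Of 17449 tested genes 10982 were called, 4928 higher and 6054 lower, and 2441 by 2-fold or more, of which 2103 were higher and 338 lower.

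MGA KO against WT asks what the loss of MGA changes. Genes of meiosis were among the largest rises, with SMC1B, a cohesin subunit of meiotic chromosomes (5.83 ± 0.21, adjusted p = 7.8e-15), CNTD1, which matures meiotic crossovers (5.71 ± 0.31), and SYCE2 (3.41 ± 0.2). Beside them rose RIPPLY2, a repressor of somite formation (23 reads against 1, ratio interval 3.8 to 965), the lymphoid transcription factor IKZF3 (4.11 ± 0.08, adjusted p = 2.83e-19), GALNT14 (4.03 ± 0.31), IFIT2 (4.01 ± 0.31), TM4SF1 (4 ± 0.34), INA (3.9 ± 0.19) and the nitric oxide synthase NOS2 (3.58 ± 0.16). The largest falls were in the splicing regulator ESRP1 (2 reads against 87, ratio interval 0.00279 to 0.0871) and the stem cell receptor LGR5 (-3.77 ± 0.15). Next came the cadherin CDH4 (-3.68 ± 0.27), EEF1AKMT1 (-3.54 ± 0.34), BST2 (-3.46 ± 0.28), ABCA8 (-3.36 ± 0.31), SPRY4, a brake on growth factor signals (-3.24 ± 0.22), and TOX3 (-3.16 ± 0.31). NPIPA2 (at least 31.8-fold lower) and EIF3CL (-4.45 ± 0.91) have near-copies and are uncertain. E2F6 rose (0.37 ± 0.05), while L3MBTL2 (-0.19 ± 0.05) and MAX (-0.18 ± 0.05) fell, neither of them with an effective length offset (adjusted p = 0.181). PCGF6 was at -0.1 ± 0.04 (adjusted p = 0.0697), and passed without WT replicate 1 (-0.16, adjusted p = 0.00648).

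Of the germline and meiosis genes 11 of 24 rose and 3 fell (12 and 3 adjusted over the list alone), median 0.38, adjusted p = 0.002, MEIOC (2.34 ± 0.07) and TAF7L (1 ± 0.06) among the rises. ER chaperones rose nearly throughout: 20 of 21 rose and 0 fell, median 0.79, adjusted p = 1.99e-18. They include HSPA5 (1.85 ± 0.03), PDIA4 (1.73 ± 0.03), HYOU1 (1.25 ± 0.03) and HSP90B1 (1.1 ± 0.03). Of the clustered protocadherins, cell surface genes that share exons and are uncertain one by one, 0 of 43 rose and 22 fell (0 and 23 adjusted over the list alone), median -0.58, adjusted p = 0.000159, PCDHA10 (-2.56 ± 0.14) and PCDHB16 (-1.18 ± 0.15) among them. Of the interferon-stimulated genes 20 of 43 rose and 6 fell, median 0.29, adjusted p = 0.000565. Of these, IFIT1 (2.5 ± 0.17) and OAS3 (0.54 ± 0.04) were higher. Of the G1/S genes 6 of 38 rose and 23 fell (6 and 24 adjusted over the list alone), median -0.19, adjusted p = 0.00168. Of these, MCM4 (-0.49 ± 0.03, window median -0.42) and MCM7 (-0.47 ± 0.03, window median -0.15) were lower. These lists, 5 of 10 called, held with an estimated correlation (adjusted p = 0.00293 to 0.0311).

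Of the immediate early genes 4 of 30 rose and 14 fell, median -0.2, adjusted p = 0.002 and adjusted p = 0.268 with an estimated correlation. Of these, ETV5 (-2.28 ± 0.1), DUSP4 (-0.95 ± 0.07) and MYC itself (-1.03 ± 0.08) were lower. Among MYC targets 3 of 40 rose and 24 fell (3 and 25 adjusted over the list alone), median -0.15, adjusted p = 0.002 and adjusted p = 0.287 with an estimated correlation. Of the ribosomal proteins 2 of 75 rose and 60 fell, median -0.15, adjusted p = 3.3e-12 and adjusted p = 0.243 with an estimated correlation. Of oxidative phosphorylation 1 of 44 rose and 23 fell (1 and 24 adjusted over the list alone), median -0.1, adjusted p = 0.00146 and adjusted p = 0.248 with an estimated correlation. For the proteasome 2 of 35 rose and 14 fell, median -0.05, adjusted p = 0.0308 and adjusted p = 0.287 with an estimated correlation. This call ended without WT replicate 3 (adjusted p = 0.0618) or MGA KO replicate 2 (adjusted p = 0.0744). The PRC1.6 members did not pass: 3 of 18 rose and 8 fell (3 and 9 adjusted over the list alone), median -0.04, adjusted p = 0.288. Neither did ATF4 targets, 13 of 34 rose and 10 fell (14 and 10 adjusted over the list alone), median 0.07, adjusted p = 0.143. DDIT3, a stress transcription factor (1.83 ± 0.09), and ALDH1L2 (2.08 ± 0.09) rose. Notch and Hedgehog targets did not pass, 1 of 13 rose and 5 fell, median -0.12, adjusted p = 0.105. In all 7096 genes were called (4406 with an effective length offset and 13832 with the other wild type as control), 3255 higher and 3841 lower, and 841 by 2-fold or more (564 higher, 277 lower).

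The double knockout against WT asks what changes with both knockouts, USP7 being at -2.56 ± 0.03. The largest rises include SOGA3, ERG, EPHA6 and the vitamin E carrier TTPA (at least 114, 46.1, 42.6 and 32.7 times higher). Then came PLPPR5, DNAJC5G, NELL1 and the pancreatic transcription factor PTF1A (at least 31.2, 27.4, 25.7 and 23.1 times higher), and CNTD1 (7.64 ± 0.22). The largest falls were in KRBOX1 and MAGEB2 (at least 51.4 and 31.6 times lower) and the transcription factor RUNX3 (-5.92 ± 0.31). Others were ZNF257 (-4.97 ± 0.45), PLBD1 (3 reads against 89, ratio interval 0.00597 to 0.0891), ALPK2 (-4.49 ± 0.3) and ZNF532 (-4.41 ± 0.14). PCDHGB5 (-7.66 ± 0.3), SPANXN3 (at least 16.4-fold lower) and the histone H3-2 (-3.83 ± 0.33) fell as well and are uncertain. PCGF6 (-0.49 ± 0.05), L3MBTL2 (-0.9 ± 0.05) and MAX (-0.31 ± 0.05) fell and E2F6 rose (0.21 ± 0.05).

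MYC targets fell as a whole: 0 of 40 rose and 40 fell, median -0.9, adjusted p = 1.88e-16. They include the chaperones HSPD1 (-1.25 ± 0.03) and HSPE1 (-1.28 ± 0.03), GNL3 (-1.49 ± 0.04) and NOP56 (-1.11 ± 0.03). MYC itself was at -2.18 ± 0.09. Of the proteasome genes 0 of 35 rose and 33 fell, median -0.38, adjusted p = 3.6e-09, PSMD2 among them (-0.87 ± 0.03). Of the G1/S genes 1 of 38 rose and 33 fell (1 and 34 adjusted over the list alone), median -0.51, adjusted p = 5.37e-10. They include the thymidylate synthase TYMS (-0.99 ± 0.03). Of the DNA repair genes 5 of 49 rose and 38 fell, median -0.44, adjusted p = 6.26e-08. They include ATR (-1.36 ± 0.05) and PRKDC (-0.85 ± 0.02). Of the interferon-stimulated genes 33 of 43 rose and 1 fell (35 and 1 adjusted over the list alone), median 0.95, adjusted p = 3.74e-08. Of these, IFIT2 (6.9 ± 0.2), IFI16 (3.92 ± 0.15) and OAS3 (1.38 ± 0.04) were higher. Neuronal markers moved with this group, 14 of 17 rose and 2 fell, median 1.32, adjusted p = 0.000936. They include INA (4.05 ± 0.18), L1CAM (1.76 ± 0.08) and NEFM (272 reads against 3, ratio interval 26.9 to 387). Of the PRC1.6 members 4 of 18 rose and 13 fell, median -0.33, adjusted p = 0.00673. They include WDR5 (-0.76 ± 0.03) and CBX3 (-0.66 ± 0.03). These lists, 7 of 15 called, held with an estimated correlation (adjusted p = 0.00164 to 0.0424).

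Of the germline genes 10 of 24 rose and 4 fell, median 0.5, adjusted p = 0.0328 and adjusted p = 0.089 with an estimated correlation. Of these, SMC1B (4.43 ± 0.25), SYCE2 (2.8 ± 0.21), TEX14 (1.51 ± 0.11) and MEIOC (1.24 ± 0.08) were higher. ER chaperones did not pass, 11 of 21 rose and 5 fell (12 and 5 adjusted over the list alone), median 0.15, adjusted p = 0.241, HSPA5 at 0.46 ± 0.03. For protocadherins 21 of 43 rose and 5 fell (20 and 5 adjusted over the list alone), median 0.5, adjusted p = 0.0449 and adjusted p = 0.0936 with an estimated correlation. Their window, 140 to 150 Mb of chromosome 5, had a median of 0.36. The list call ended without any single library of WT or the double knockout except WT replicate 1 (adjusted p = 0.0506 to 0.062). For immediate early genes 18 of 30 rose and 6 fell, median 0.41, adjusted p = 0.0331 and adjusted p = 0.405 with an estimated correlation. This call ended without double knockout replicate 1 (adjusted p = 0.0523). For the USP family 9 of 43 rose and 22 fell, median -0.12, adjusted p = 0.0443 and adjusted p = 0.232 with an estimated correlation. It ended without double knockout replicate 3 (adjusted p = 0.0567). Of oxidative phosphorylation 1 of 44 rose and 35 fell (1 and 36 adjusted over the list alone), median -0.21, adjusted p = 1.28e-05 and adjusted p = 0.11 with an estimated correlation. Of cholesterol synthesis 4 of 24 rose and 17 fell, median -0.43, adjusted p = 0.00673 and adjusted p = 0.11 with an estimated correlation. ACAT2 was among the falls (-1.43 ± 0.05). Of the partners of USP7 4 of 29 rose and 19 fell, median -0.25, adjusted p = 0.0115 and adjusted p = 0.11 with an estimated correlation. Of the 8 blood and endothelial markers tested 6 rose and 0 fell, median 1.13, adjusted p = 0.0412 and adjusted p = 0.11 with an estimated correlation. Of the 17449 genes 11594 were called, 5703 higher and 5891 lower, and 2564 by 2-fold or more (2069 higher, 495 lower).

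The double knockout against MGA KO asks what the USP7 knockout adds to the MGA knockout, though MGA also differed (-0.59 ± 0.05) beside USP7 (-2.5 ± 0.03). The window from 40 to 50 Mb of chromosome 15, which holds MGA, had a median of -0.48 here and -0.52 against WT. The largest rises were in SOGA3 (at least 112-fold higher) and the neuronal migration gene ASTN1 (547 reads against 1, ratio interval 84.1 to 18600). After these came SLITRK3 (at least 37.5-fold higher) and NELL1 (at least 25.2-fold higher). Beside these stood the neuropeptide receptors NPY1R (at least 20.9-fold higher) and NMUR2 (224 reads against 1, ratio interval 34.2 to 7640), and KIAA0408 (589 reads against 3, ratio interval 57.5 to 821). The largest falls were in IQCA1, MAGEB2 and KRBOX1 (at least 76.4, 16.7 and 13.6 times lower). RUNX3 (-6.34 ± 0.29), ZNF532 (-5.72 ± 0.12), DLGAP1 (-5.17 ± 0.33) and the receptor kinase AXL (-4.81 ± 0.09) followed. NPIPA2, PRSS3 and MAGED4 (at least 64.5, 45.9 and 31.2 times higher) are uncertain, as are PCDHGB5 (-6.63 ± 0.35), SPANXN3 (at least 4.65-fold lower) and H3-2 (-4.53 ± 0.3). MAGED4 did not pass with all 18 libraries in the fit (adjusted p = 0.054). PCGF6 (-0.39 ± 0.05) and L3MBTL2 (-0.71 ± 0.05) fell. E2F6 was at -0.16 ± 0.05 (adjusted p = 0.012), which ended without double knockout replicate 1 (adjusted p = 0.056) and with an effective length offset (adjusted p = 0.0697). MAX was at -0.13 ± 0.05 (adjusted p = 0.0187), which ended with DESeq2 (adjusted p = 0.0769), with an effective length offset (adjusted p = 0.508) and without double knockout replicate 2 (adjusted p = 0.0881) or 3 (adjusted p = 0.0633).

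ER chaperones fell here: 3 of 21 rose and 18 fell, median -0.84, adjusted p = 6.29e-07. They include PDIA4 (-1.9 ± 0.03) and HSPA5 (-1.39 ± 0.03). Of the MYC targets 0 of 40 rose and 39 fell (1 and 39 adjusted over the list alone), median -0.73, adjusted p = 9.37e-15. They include NOP56 (-1.49 ± 0.03) and HSPD1 (-1.2 ± 0.03). Of the proteasome 2 of 35 rose and 31 fell, median -0.3, adjusted p = 6.29e-07. Of the G1/S genes 5 of 38 rose and 30 fell, median -0.43, adjusted p = 2.1e-06. Of the DNA repair genes 6 of 49 rose and 36 fell, median -0.35, adjusted p = 5.82e-06. Of the interferon-stimulated genes 32 of 43 rose and 4 fell, median 0.93, adjusted p = 2.23e-05. IFI16 was among the rises (6.69 ± 0.22). Of the protocadherins 30 of 43 rose and 3 fell (31 and 3 adjusted over the list alone), median 1.08, adjusted p = 4.82e-05. Their window was at 0.42. Of the PRC1.6 members 3 of 18 rose and 14 fell, median -0.31, adjusted p = 0.00308. These lists, 8 of 16 called, held with an estimated correlation (adjusted p = 0.00873 to 0.0372). Germline genes did not pass, 5 of 24 rose and 7 fell, median -0.17, adjusted p = 0.755. Of these, SMC1B (-1.39 ± 0.11) and MEIOC (-1.09 ± 0.06) were lower. Of the immediate early genes 21 of 30 rose and 4 fell, median 0.63, adjusted p = 9.61e-05 and adjusted p = 0.136 with an estimated correlation. SPRY4 was among the rises (4.42 ± 0.18). Of Wnt targets 13 of 20 rose and 3 fell, median 0.62, adjusted p = 0.00438 and adjusted p = 0.0659 with an estimated correlation. Of neuronal markers 11 of 17 rose and 1 fell, median 0.85, adjusted p = 0.00483 and adjusted p = 0.0502 with an estimated correlation. Of ATF4 targets 8 of 34 rose and 20 fell, median -0.3, adjusted p = 0.0093 and adjusted p = 0.136 with an estimated correlation. Of oxidative phosphorylation 7 of 44 rose and 21 fell, median -0.09, adjusted p = 0.0358 and adjusted p = 0.423 with an estimated correlation. That ended without MGA KO replicate 3 (adjusted p = 0.0576) or double knockout replicate 1 (adjusted p = 0.0607). Of cholesterol synthesis 5 of 24 rose and 17 fell, median -0.36, adjusted p = 0.00438 and adjusted p = 0.0975 with an estimated correlation. Of the ribosomal proteins 47 of 75 rose and 20 fell (48 and 20 adjusted over the list alone), median 0.16, adjusted p = 0.0022 and adjusted p = 0.527 with an estimated correlation. Of the partners of USP7 5 of 29 rose and 17 fell (5 and 18 adjusted over the list alone), median -0.25, adjusted p = 0.013 and adjusted p = 0.135 with an estimated correlation. Of 11015 called genes 5467 were higher and 5548 lower, and 2202 differed by 2-fold or more (1677 higher, 525 lower).

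The double knockout against USP7 KO#41 asks what the MGA knockout adds to the USP7 knockout. The largest rises were in the Wnt inhibitor WIF1 (at least 83.6-fold higher), IRF5 (at least 71.9-fold higher) and FOXL2 (at least 38.7-fold higher). Next came RAMP2 (at least 34.7-fold higher), the retinoic acid carrier CRABP1 (at least 27.7-fold higher) and RBP4 (at least 23.1-fold higher). Then came BNC1 (301 reads against 2, ratio interval 38.1 to 1150) and the blood transcription factor TAL1 (275 reads against 2, ratio interval 34.8 to 1050). The largest falls were in IQCA1 (at least 56.7-fold lower), RUNX3 (-7.02 ± 0.26) and TMEM35A (1 read against 95, ratio interval 0.000243 to 0.0554). Others were BEX1 (-5.6 ± 0.15), THBS2 (-5.49 ± 0.16) and IL1R2 (2 reads against 79, ratio interval 0.00278 to 0.0872). After these came DLGAP1 (-5.07 ± 0.33), ZNF532 (-4.78 ± 0.13) and TDO2 (2 reads against 50, ratio interval 0.00435 to 0.14). PRSS3 (at least 49.2-fold higher), F8A1 (at least 18.1-fold higher) and H3-2 (-4.97 ± 0.28) are uncertain. USP7 was at 0.08 ± 0.03 (adjusted p = 0.046), which ended with RLE scaling (adjusted p = 0.157), DESeq2 (adjusted p = 0.284), no count filter (adjusted p = 0.548), the replicate block (adjusted p = 0.056), only these groups (adjusted p = 0.0868) and all 18 libraries in the fit (adjusted p = 0.341). It also ended without any single library except USP7 KO#41 replicate 3 (adjusted p = 0.0655 to 0.175), but stood at 0.45 with an effective length offset. MGA fell (-1.71 ± 0.04). PCGF6 rose (0.18 ± 0.05), and L3MBTL2 (-0.4 ± 0.06), E2F6 (-0.21 ± 0.05) and MAX (-0.17 ± 0.05) fell. Of the p53 targets 23 of 34 rose and 5 fell, median 0.36, adjusted p = 0.00027 and adjusted p = 0.363 with an estimated correlation. Of these, CCNG1 (0.81 ± 0.03), PLK2 (0.87 ± 0.04) and TP53INP1 (1.31 ± 0.07) were higher. Of the MYC targets 2 of 40 rose and 37 fell, median -0.55, adjusted p = 1.23e-12 and adjusted p = 0.223 with an estimated correlation. Of G2/M 24 of 36 rose and 7 fell, median 0.22, adjusted p = 0.000749 and adjusted p = 0.43 with an estimated correlation. Of the proteasome 4 of 35 rose and 23 fell (5 and 23 adjusted over the list alone), median -0.18, adjusted p = 0.000749 and adjusted p = 0.384 with an estimated correlation. None of the 4 held with an estimated correlation. Germline genes did not pass, 10 of 24 rose and 6 fell (10 and 7 adjusted over the list alone), median 0.28, adjusted p = 0.556. Of 9899 called genes 4935 were higher and 4964 lower, and 1278 differed by 2-fold or more (566 higher, 712 lower).

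**Figure D2:**
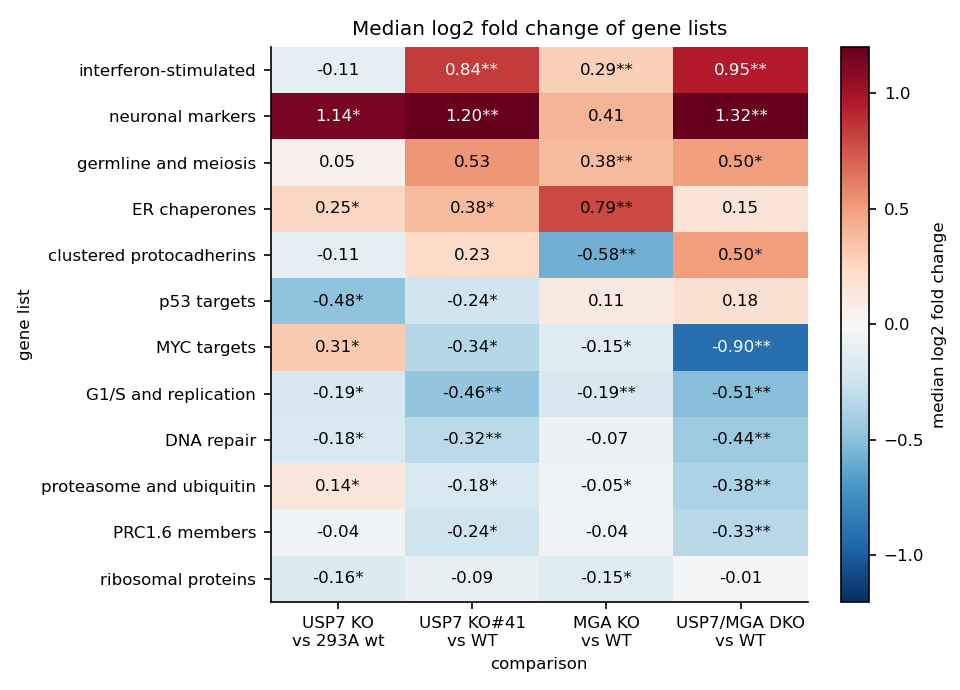
Median log2 fold change of 12 gene lists in 4 comparisons, with 1 star for an adjusted p under 0.05 by camera at the preset correlation and 2 stars where it also held with an estimated correlation. ER chaperones had a median of 0.79 in MGA KO against WT and 0.15 in the double knockout against WT.

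**Figure D3:**
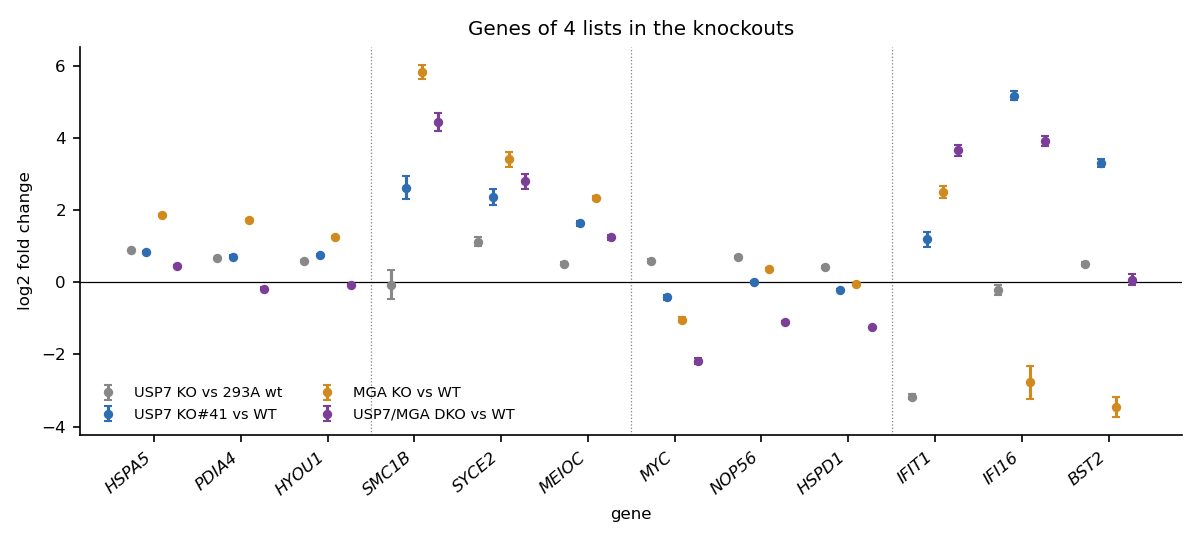
Log2 fold change with standard error of 12 named genes in 4 comparisons, from 3 libraries per group. HSPA5 was at 1.85 in MGA KO against WT and at 0.46 in the double knockout against WT.

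The interaction asks whether the double knockout departs from the sum of the single knockouts, taking the USP7 loss to act as in USP7 KO#41. By the smallest adjusted p, the genes above the sum were the actin crosslinker FLNA (2.34 ± 0.03), COL2A1 (9 ± 0.15), COL12A1 (2.09 ± 0.05), fibronectin FN1 (1.85 ± 0.04), ID4 (2.78 ± 0.05) and CA5B (3.88 ± 0.08). HSPA5 (-2.23 ± 0.04), PDIA4 (-2.61 ± 0.05), HYOU1 (-2.08 ± 0.05), AXL (-6.55 ± 0.12), ZNF532 (-6.08 ± 0.15) and IKZF3 (-3.8 ± 0.09) stood below it. The only list that held with an estimated correlation (adjusted p = 0.0196) was ER chaperones, where 1 of 21 rose and 18 fell, median -0.98, adjusted p = 1.6e-10. Of 8984 called genes 4614 were above the sum and 4370 below, and 1977 departed by 2-fold or more (753 above, 1224 below). With the USP7 effect taken from USP7 KO and 293A wt most 2-fold departures were above, 1608 against 1038 below.

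The next question is whether the knockouts move the same genes. USP7 KO and USP7 KO#41, with no library in common, had a rank correlation of log2 fold changes of 0.41 (Pearson's r 0.616) over 17374 genes, which are not independent replicates. In both, 832 genes rose 2-fold or more (122.6 for independent lists, Fisher's exact p = 1e-300 or less), 154 fell (10.4, p = 1.89e-146) and 70 went opposite ways. Opposite counts here and below have no such value, so the p-values alone do not show a shared direction. The labels do not say whether these groups share a clone. Genes that rose most in both include NELL1, PLPPR5, SOGA3, ADAMTS12, CACNG7, FGFBP1 and TMEM229A, and those that fell most in both include IRF5, FOXL2, KRBOX1, F8A3, DTX3, SPANXN3, COL2A1 and GALC. FGFBP1 averaged 0.407 TPM in 293A wt, 24.6 in USP7 KO, 0.415 in WT and 22.3 in USP7 KO#41. USP7 KO against 293A wt and the double knockout against MGA KO had a correlation of 0.185, with 592 genes higher in both (97.5), 114 lower (16.3) and 150 opposite. USP7 KO#41 against WT and that comparison, also with no library in common, had 0.407, with 942 genes higher in both (202.1), 88 lower (10.2) and 132 opposite.

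USP7 KO and MGA KO, also without a shared library, had a rank correlation of 0.051 (Pearson's r 0.12), with 173 genes higher in both (32.8 for independent lists, p = 6.55e-80), 60 lower (8.6, p = 1.15e-33) and 111 opposite. RIPPLY2, GALNT14, IKZF3, NOS2, INA, EGR2, PGR and CNTD1 rose in both. ESRP1, CDH4, ABCA8, COL2A1, KRBOX1, SPANXN3, DACH1 and TSC22D3 fell in both, SPANXN3 being uncertain. IKZF3 averaged 0.352 TPM in 293A wt, 5.98 in USP7 KO, 0.504 in WT, 9.47 in MGA KO and 11.2 in the double knockout. USP7 KO#41 and MGA KO share the WT libraries, and their correlation was 0.449 where simulated unchanged groups gave 0.443 (0.422 to 0.458 in 20 simulations). The covariance was 0.2612 against 0.0214 simulated, a difference of 0.2398. In both, 398 genes were higher (68), 57 lower (5.4) and 74 opposite, where the simulations gave a mean of 0.1 higher and 0.1 lower. CNTD1, RIPPLY2, GALNT14, IKZF3, NOS2, INA, C5 and EGR2 led the rises and ESRP1, GATD3B, PUDP, PCDHA10, LGR5, COL2A1, CBS and CDH4 the falls, GATD3B, CBS and PCDHA10 being uncertain. The 3 WT libraries do not make sets of 2 for each side, so part of the excess in the overlap may come from the shared controls. MGA KO against WT and the double knockout against USP7 KO#41, with no shared library, had a correlation of -0.052. In both, 53 genes were higher (18.3), 40 lower (11.3) and 148 opposite, so only 38.6% had the same sign.

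**Figure D4:**
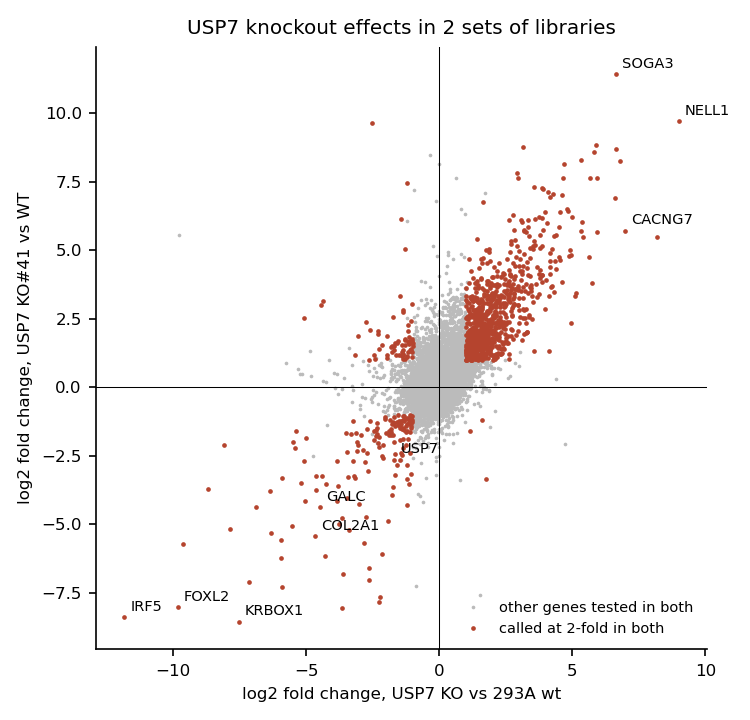
Log2 fold changes of all genes tested in USP7 KO against 293A wt (horizontal) and USP7 KO#41 against WT (vertical), with genes called at 2-fold in both in red. Of 1056 such genes 93.4% have the same sign, and the positions of genes with near-zero counts depend on the prior count.

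A single fit set the effects of the USP7 knockouts against each other, so the gap between the wild types enters too. The effect was higher in USP7 KO for GPRC5A (1.92 ± 0.04), DEPP1 (2.08 ± 0.06), the chaperone HSPH1 (1.26 ± 0.04), the nucleolar helicase DDX21 (1.21 ± 0.03), PCDH9 (2.55 ± 0.08) and ODC1 (1.08 ± 0.03). It was higher in USP7 KO#41 for the collagen receptor DDR2 (-4.37 ± 0.13), IL32 (-3.16 ± 0.1), FHAD1 (-2.44 ± 0.08), IFI16 (-5.41 ± 0.19) and GPNMB (-3.83 ± 0.13). Of the MYC targets 39 of 40 rose and 0 fell, median 0.65, adjusted p = 2.09e-17. Of the interferon-stimulated genes 4 of 45 rose and 32 fell (4 and 33 adjusted over the list alone), median -0.84, adjusted p = 7.26e-10. Both held with an estimated correlation (adjusted p = 0.0126 and 0.000147). Here rose and fell mean a higher effect in USP7 KO or in USP7 KO#41. Of 9761 called genes 5394 had the higher effect in USP7 KO and 4367 in USP7 KO#41, and 2097 differed by 2-fold or more (260 and 1837). Along the chromosomes, 36 windows of 10 Mb (GRCh38) had medians shifted by 0.15 or more the same way in both USP7 comparisons, 30 of them lower, and 4 opposite ways. The window at 70 to 80 Mb of chromosome 13 had medians of -0.78 in USP7 KO and -0.99 in USP7 KO#41, and that at 0 to 10 Mb of chromosome 10 had 0.64 and 0.38. In the double knockout against MGA KO 110 windows were shifted, 5 of chromosome 3 between 0 and 60 Mb at -0.66 to -0.49. The standard deviation of window medians was 0.242 there (0.091 with shuffled positions) and 0.137 in MGA KO against WT (0.048).

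**Figure D5:**
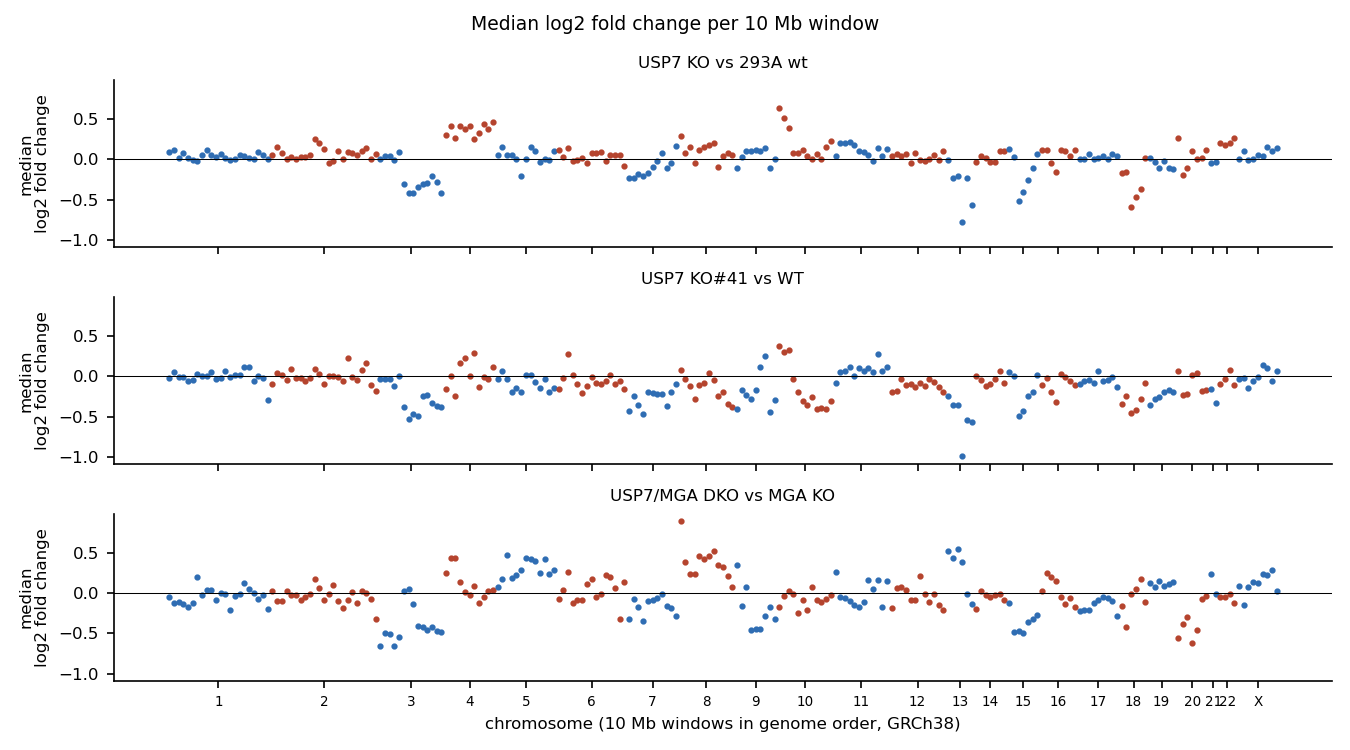
Median log2 fold change of coding genes in 10 Mb windows along the chromosomes (GRCh38) in USP7 KO, USP7 KO#41 and the double knockout against MGA KO. Window medians correlate at 0.722 between the USP7 knockouts and at 0.159 between USP7 KO and the double knockout against MGA KO.

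WT against 293A wt sets the wild types side by side, as a background for comparisons across the sets of libraries, which also differ in depth. Interferon genes were lower in WT: IFNB1, IFNL1 and IFI44 (at least 11.6, 9.35 and 17 times lower), IFIT2 (-7.37 ± 0.17) and OASL (2 reads against 1093, ratio interval 0.000734 to 0.022). So were EBI3, PTGDS and TNFRSF18 (at least 11.5, 13.4 and 9.45 times lower). Chaperones HSPH1 (2.25 ± 0.03) and HSPA1A (2.39 ± 0.24, a near-copy of HSPA1B and uncertain), PRRG3 (241 reads against 3, ratio interval 90.1 to 1300), the collagen COL6A3 (5.73 ± 0.19), LGR5 (2.17 ± 0.1), LYAR (2.16 ± 0.05), ASDURF (4.25 ± 0.82) and the mitochondrial MT-ND6 (2.17 ± 0.19) were higher. EIF5AL1 (2.34 ± 0.2), SERF1A (2.14 ± 0.44), FAM220A (at least 63.5-fold lower) and the readthrough GET1-SH3BGR (at least 11.2-fold lower) are uncertain. The GET1-SH3BGR call ended with an effective length offset (adjusted p = 0.0695) and without 293A wt replicate 1 (adjusted p = 0.143) or any single WT library (adjusted p = 0.0679 to 0.0769). USP7 (1.14 ± 0.02), MGA (0.61 ± 0.04), PCGF6 (0.79 ± 0.04), L3MBTL2 (0.66 ± 0.04), E2F6 (0.48 ± 0.05) and MAX (0.95 ± 0.04) were all higher in WT. Of the interferon-stimulated genes 3 of 45 rose and 34 fell (3 and 35 adjusted over the list alone), median -0.98, adjusted p = 6.02e-06. Of the MYC targets 37 of 40 rose and 3 fell, median 1, adjusted p = 1.91e-11. Of G1/S 29 of 38 rose and 7 fell, median 0.36, adjusted p = 0.000168. Of the PRC1.6 members 14 of 18 rose and 3 fell, median 0.53, adjusted p = 0.000912. Of the partners of USP7 22 of 29 rose and 4 fell (23 and 4 adjusted over the list alone), median 0.44, adjusted p = 0.000171. Of the USP family 29 of 43 rose and 7 fell, median 0.37, adjusted p = 0.000535. Of DNA repair 33 of 49 rose and 9 fell, median 0.44, adjusted p = 0.000703. These 7 of 12 called lists held with an estimated correlation (adjusted p = 0.00185 to 0.0413). Of 18472 tested genes 13995 were called, 6731 higher and 7264 lower, and 4138 by 2-fold or more (884 higher, 3254 lower). With the other wild type, from the other set, the 2-fold calls went from 2351 to 4611 in USP7 KO, 2441 to 3694 in USP7 KO#41 and 841 to 3881 in MGA KO. With it PCGF6 in USP7 KO was at -0.8 (adjusted p = 2.89e-14). The sign turned for MGA, L3MBTL2, MAX, SRM, ODC1, DUSP1, IFIT2 and IFIT1 in USP7 KO and for PCGF6, L3MBTL2, MAX, POLA1, PRKDC, NOLC1, PDIA4, CBX3 and GMPS in USP7 KO#41. It also turned for USP7, L3MBTL2, MAX, PCGF6, IFIT1, IFIT2, OAS3 and DDIT3 in MGA KO and for PCGF6, MAX, HSPD1, HSPE1, IFIT2 and HSPA5 in the double knockout. The calls of IFNB1, CSAG3, E2F6, BAX, TP53INP1, NOP56, MAGEA10 and MYC in USP7 KO, of L1CAM and GADD45A in USP7 KO#41, and of PRKDC and CBX3 in the double knockout ended with it.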

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

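The tests by regrouping in this part were chosen after the result was seen. The interaction called 8984 genes, 1977 of them by 2-fold or more. Of 60 groupings of the libraries, the real one and others drawn at random, 2 gave as many calls, the real one included, and the highest other gave 11979. That split puts WT and MGA KO on one side and USP7 KO#41 and the double knockout on the other, so it holds the USP7 knockout contrast, and in all 3 other splits called more than 1000 genes, which points to structure in the data beyond the interaction. The difference of the USP7 knockout effects called 9761 genes, 2097 by 2-fold or more, where 1 of 60 groupings, the real one, gave as many, the highest other split gave 6528, and in all 5 other splits called more than 1000, which again points to structure.

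For the interaction, the values were 0.14 ± 0.04 for USP7 (adjusted p = 0.00634), -0.97 ± 0.06 for MGA, 0.28 ± 0.07 for PCGF6, -0.21 ± 0.07 for L3MBTL2 (adjusted p = 0.0222) and -0.57 ± 0.07 for E2F6, while MAX was at 0.01 ± 0.07 (adjusted p = 0.949). The USP7 call ended with DESeq2 (adjusted p = 0.0667), without MGA KO replicate 2 (0.10, adjusted p = 0.0602), without MGA KO replicate 3 (adjusted p = 0.0511) and without the count filter (adjusted p = 0.145), and it stood at 0.51 with an effective length offset. The L3MBTL2 call ended with an effective length offset (adjusted p = 0.121) and without WT replicate 2, MGA KO replicate 1, double knockout replicate 3 or USP7 KO#41 replicate 2 (adjusted p = 0.0687 to 0.0925). Above the sum stood FLNA (2.34), COL2A1 (9), ID4 (2.78), CA5B (3.88), COL12A1 (2.09) and FN1 (1.85), and below it HSPA5 (-2.23), PDIA4 (-2.61), AXL (-6.55), HYOU1 (-2.08), ZNF532 (-6.08) and IKZF3 (-3.8). In the lists, rose and fell mean above and below the sum. For ER chaperones 1 of 21 rose and 18 fell, median -0.98, adjusted p = 1.6e-10. They alone held with an estimated correlation (adjusted p = 0.0196). For protocadherins 20 of 43 rose and 3 fell (21 and 4 adjusted over the list alone), median 0.82, adjusted p = 0.00383 and adjusted p = 0.0557 with an estimated correlation. Their 10 Mb window had medians of 0.36 in the double knockout, -0.04 in USP7 KO#41 and -0.06 in MGA KO, each against WT. For immediate early genes 19 of 30 rose and 6 fell, median 0.55, adjusted p = 0.00383 and adjusted p = 0.329 with an estimated correlation. For MYC targets 3 of 40 rose and 27 fell (3 and 29 adjusted over the list alone), median -0.37, adjusted p = 3.11e-06 and adjusted p = 0.229 with an estimated correlation. For p53 targets 19 of 34 rose and 6 fell (19 and 7 adjusted over the list alone), median 0.32, adjusted p = 0.0117 and adjusted p = 0.282 with an estimated correlation. For ribosomal proteins 47 of 75 rose and 10 fell (49 and 10 adjusted over the list alone), median 0.18, adjusted p = 3.55e-05 and adjusted p = 0.445 with an estimated correlation. For G2/M 16 of 36 rose and 5 fell (18 and 5 adjusted over the list alone), median 0.13, adjusted p = 0.0399 and adjusted p = 0.502 with an estimated correlation. This call ended with RLE scaling (adjusted p = 0.0569) and without WT replicate 3, MGA KO replicate 1 or 3, double knockout replicate 1, or USP7 KO#41 replicate 2 or 3 (adjusted p = 0.0518 to 0.101). For Notch and Hedgehog targets 8 of 13 rose and 2 fell, median 0.42, adjusted p = 0.0399 and adjusted p = 0.229 with an estimated correlation. This call ended without WT replicate 3 (adjusted p = 0.0518) or USP7 KO#41 replicate 2 (adjusted p = 0.0519).

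For the difference of the USP7 knockout effects, the values were 0.94 ± 0.04 for USP7, 0.63 ± 0.07 for PCGF6, 0.75 ± 0.06 for L3MBTL2 and 0.32 ± 0.06 for MAX (adjusted p = 0.349 with an effective length offset), while MGA (0.03 ± 0.05, adjusted p = 0.685) and E2F6 (0.11 ± 0.06, adjusted p = 0.131) did not pass. Higher in USP7 KO were the effects on GPRC5A (1.92), DEPP1 (2.08), HSPH1 (1.26), DDX21 (1.21), PCDH9 (2.55) and ODC1 (1.08). Higher in USP7 KO#41 were those on DDR2 (-4.37), IL32 (-3.16), FHAD1 (-2.44), IFI16 (-5.41) and GPNMB (-3.83). Here rose and fell mean a higher effect in USP7 KO or in USP7 KO#41. For MYC targets 39 of 40 rose and 0 fell, median 0.65, adjusted p = 2.09e-17. For the proteasome 29 of 35 rose and 0 fell, median 0.28, adjusted p = 4.52e-09. For G2/M 28 of 36 rose and 1 fell, median 0.27, adjusted p = 3.34e-08. For G1/S 28 of 38 rose and 2 fell (29 and 2 adjusted over the list alone), median 0.28, adjusted p = 7.75e-07. For DNA repair 23 of 49 rose and 5 fell, median 0.17, adjusted p = 0.0091. For interferon-stimulated genes 4 of 45 rose and 32 fell (4 and 33 adjusted over the list alone), median -0.84, adjusted p = 7.26e-10. For p53 targets 1 of 34 rose and 20 fell (2 and 21 adjusted over the list alone), median -0.24, adjusted p = 3.08e-06. For matrix and adhesion 8 of 38 rose and 20 fell (8 and 21 adjusted over the list alone), median -0.19, adjusted p = 0.0145. For X-linked cancer-testis genes 0 of 9 rose and 1 fell, median -1.76, adjusted p = 0.0094. For PRC1.6 10 of 18 rose and 1 fell, median 0.29, adjusted p = 0.00291. For the PRC1 and PRC2 core 16 of 34 rose and 6 fell, median 0.15, adjusted p = 0.0094. For the partners of USP7 15 of 29 rose and 5 fell, median 0.19, adjusted p = 0.0219. Their mean was -0.02 beside a positive median. These 12 lists held with an estimated correlation (adjusted p = 0.000147 to 0.047). For ATF4 targets 18 of 34 rose and 8 fell, median 0.28, adjusted p = 0.0219 and adjusted p = 0.136 with an estimated correlation. For ribosomal proteins 12 of 75 rose and 38 fell (12 and 41 adjusted over the list alone), median -0.09, adjusted p = 0.00342 and adjusted p = 0.534 with an estimated correlation. For the USP family 20 of 43 rose and 5 fell, median 0.16, adjusted p = 0.0094 and adjusted p = 0.0815 with an estimated correlation.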

How the results depend on the processing

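Many results depend on the control, and the labels do not pair the wild types with the knockouts. With the other wild type as control, 4611 genes were called at 2-fold in USP7 KO, 3694 in USP7 KO#41 and 3881 in MGA KO, and 13832 genes were called at any fold in MGA KO. Of the 2-fold calls of USP7 KO tested both ways, 1383 of 1904 kept their sign and 157 turned. In USP7 KO#41 1611 of 2441 kept it and 319 turned, in MGA KO 469 of 841 and 151, and in the double knockout 1631 of 2564 and 336. The share of 2-fold calls that were higher went to 77.4%, 46.8%, 25.6% and 40.2%. PCGF6 in USP7 KO went from -0.04 to -0.8 (adjusted p = 2.89e-14).

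The signs of named genes turned as follows with the other wild type. In USP7 KO these were MGA (-0.16), L3MBTL2 (-0.38), MAX (-0.73), BAX (0.02), TP53INP1 (0.04), SRM (-0.2), ODC1 (-0.83), DUSP1 (-0.42), IFIT2 (3.01) and IFIT1 (1.57). In USP7 KO#41 they were PCGF6 (0.15), L3MBTL2 (0.2), MAX (0.84), POLA1 (0.1), PRKDC (0.39), L1CAM (-0.1), NOLC1 (0.68), PDIA4 (-0.12), CBX3 (0.14) and GMPS (0.25). In MGA KO they were USP7 (1.08), IFIT2 (-3.33), IFIT1 (-2.21), L3MBTL2 (0.48), MAX (0.78), PCGF6 (0.69), OAS3 (-0.1) and DDIT3 (-0.42). In the double knockout they were PCGF6 (0.29), MAX (0.63), HSPD1 (0.17), HSPE1 (0.29), PRKDC (0.04), IFIT2 (-0.44) and HSPA5 (-0.09). With the USP7 effect taken from USP7 KO and 293A wt, the interaction turned for USP7 (-0.84), PCGF6 (-0.39) and MAX (-0.36). Of its 1977 departures of 2-fold or more 1362 kept their sign and 84 turned. The share of all its calls above the sum, 51.4%, was 45.3% with that effect, 48.3% with RLE, 49.1% with DESeq2, 47.1% without a filter, 45.8% with all 18 libraries in the fit and 46.2% or 46.1% without MGA KO replicate 2 or 3. In USP7 KO#41 the share of calls that were higher went from 44.9% to 50.2% with only the groups compared and 50.1% with all 18 libraries. In the double knockout against USP7 KO#41 it went from 49.9% to 43.8% with all 18 libraries, 44.7% without a filter, 46.6% with RLE or DESeq2 and up to 50.4% with 1 library left out. In WT against 293A wt it went to 37.4% without a filter.

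With an effective length offset 4406 genes were called in MGA KO. USP7 in MGA KO was at -0.06 with that offset (adjusted p = 0.402) and at -0.06 with DESeq2 (adjusted p = 0.145), and it ranged from -0.07 to -0.05 with 1 library left out. In the double knockout against USP7 KO#41 it was at 0.45 with the offset, at 0.06 with DESeq2 (adjusted p = 0.284) and ranged from 0.06 to 0.1. In the interaction it was at 0.51 with the offset, at 0.11 with DESeq2 (adjusted p = 0.0667) and ranged from 0.1 to 0.16. No left-out library, DESeq2 or RLE setting moved a count of called genes by more than 1.5 times.

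With an estimated correlation camera called 0 lists in USP7 KO, 4 in USP7 KO#41, 5 in MGA KO, 7 in the double knockout against WT, 8 against MGA KO, 0 against USP7 KO#41, 1 in the interaction and 7 in WT against 293A wt. With fry, which asks whether a list changes without setting it against other genes, the lists called were 25 in USP7 KO, 28 in MGA KO, 26 in the double knockout against WT, 29 against MGA KO and 25 against USP7 KO#41. They were 25 in the interaction, 25 in the difference of the USP7 effects and 27 in WT against 293A wt.

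The rank correlation of USP7 KO and USP7 KO#41 was 0.454 over genes with a mean count above 100, and Pearson's r was 0.616. For USP7 KO and MGA KO these were 0.075 and 0.12. With 1 library left out the rank correlations ranged from 0.397 to 0.413, from 0.045 to 0.057, and from 0.429 to 0.465 for USP7 KO#41 and MGA KO. Without a count filter, the median gene in WT against 293A wt moved by -0.143.

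Replicate numbers do not pair the samples: libraries with the same number correlated at -0.128 to -0.012 in the deeper set and at -0.134 to 0.057 in the other. With the number as a block, 12368 genes were called in USP7 KO, 10883 in USP7 KO#41, 6946 in MGA KO and 11473 in the double knockout. With the block the ATF4 list in USP7 KO ended (adjusted p = 0.0677) and the germline list in USP7 KO#41 passed (adjusted p = 0.0471). The block also ended the USP7 calls in MGA KO (adjusted p = 0.0622) and in the double knockout against USP7 KO#41 (adjusted p = 0.056).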

Other observations

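The remaining lists were mixed in USP7 KO against 293A wt. Of the HOX genes, which set position along the body axis, 13 of 38 rose and 9 fell, median 0.03, adjusted p = 0.825. Of the imprinted genes 6 of 19 rose and 7 fell, median 0.06, adjusted p = 0.857. The growth factor IGF2 was among the rises (1.2 ± 0.06). Of the hypoxia and glycolysis genes 9 of 24 rose and 12 fell, median -0.11, adjusted p = 0.586. PFKFB3 was among the rises (1.37 ± 0.03). Of the MAX and MYC network 4 of 13 rose and 7 fell, median -0.14, adjusted p = 0.513. MYC was among the rises (0.58 ± 0.05). Of the matrix and adhesion genes 15 of 38 rose and 18 fell, median -0.07, adjusted p = 0.233. Falls were in CCN2 (-1.73 ± 0.03), COL5A1 (-1.25 ± 0.03), COL3A1 (-4.62 ± 0.1) and TPM1 (-1.71 ± 0.04). Of the epithelial markers 5 of 16 rose and 10 fell, median -0.37, adjusted p = 0.138. Of the cholesterol genes 7 of 25 rose and 15 fell, median -0.14, adjusted p = 0.106, HMGCS1 among the falls (-0.85 ± 0.02). In MGA KO against WT these lists did not pass either: for HOX genes 6 of 36 rose and 8 fell, median -0.08, adjusted p = 0.425. For imprinted genes 5 of 17 rose and 3 fell, median 0, adjusted p = 0.572. For hypoxia 10 of 23 rose and 5 fell (10 and 6 adjusted over the list alone), median 0.13, adjusted p = 0.0772. For the MAX and MYC network 0 of 13 rose and 4 fell, median -0.11, adjusted p = 0.0646. For epithelial markers 4 of 14 rose and 2 fell, median 0.06, adjusted p = 0.835. For neuronal markers 6 of 17 rose and 2 fell, median 0.41, adjusted p = 0.0796. The network passed without WT replicate 2 (adjusted p = 0.0458) and the neuronal markers without MGA KO replicate 2 (adjusted p = 0.045). The median, the mean and the direction of the test differ in sign in 41 of 270 list tests, 2 of them called: the partners of USP7 in USP7 KO#41 against WT and in the difference of the USP7 effects.

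The tests of background reads and of loss of USP7 in the first pattern, of a shared clone and of loss of USP7 in the second, and all regroupings were chosen after the result was seen. In USP7 KO#41 against WT, 2103 genes rose by 2-fold or more and 338 fell. Unequal depth of the libraries is argued against, since 86.3% of the 2-fold calls were rises after thinning to the smallest total. Background reads from DNA or unspliced RNA are argued against as well, since the median gain per kilobase of the genes that rose was 46.5 times the mean gain of olfactory receptor genes, which are silent in most cells (bootstrap interval 16 to 350). Loss of USP7 stays open as a hypothesis found on the same data: in the double knockout against MGA KO, 84.5% of the genes that rose lay above 0, against 57.1% of genes matched on abundance. A property of the clone may add to it and was not tested for this pattern.

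In the second pattern, whole 10 Mb windows shift together in USP7 KO and USP7 KO#41, with a correlation of window medians of 0.722 (interval 0.624 to 0.796) over 237 windows. Loss of USP7 alone is argued against, since the windows of USP7 KO and of the double knockout against MGA KO correlate at 0.159 (interval 0.015 to 0.294), though 15 of the 36 windows alike in both also shift alike there. GC content or length of the genes is argued against, since the correlation stays at 0.72 after removing both trends. Cells of one clone with altered copy number stay open, and the labels do not say whether the groups share a clone. Windows also shift in MGA KO and the double knockout, so altered copy number, not tested there, may bear on their results and the interaction. With window medians removed, the rank correlation of the genes went from 0.487 to 0.444 over 12132 genes.

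In the third pattern, 4138 genes differ by 2-fold or more between WT and 293A wt, which carry no knockout label. GC content as the whole cause is argued against, since 3307 genes (79.9% as many) were called at 2-fold after an offset for it. Only 2689 of them were among the 4138, so GC content stays open as a part of the cause. Unequal depth is argued against, since 3912 genes (94.5% as many) were called after thinning. A difference between the sets of libraries that wild type and knockout share stays open for part of these genes, since 1160 of them differ by 2-fold or more the same way in USP7 KO#41 against USP7 KO, with no library in common. The rank correlation over all genes was 0.632 (Pearson's r 0.507, by rank 0.513 after the GC offset), and no biological explanation was tested.

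For the comparisons of 3 against 3 libraries, 10 splits are too few for a share under 0.05, so each has 1 of 10 at best. The real split called 12683 genes in USP7 KO against 293A wt, 10982 in USP7 KO#41 against WT, 7096 in MGA KO against WT, 11594 and 11015 in the double knockout against WT and MGA KO, 9899 against USP7 KO#41 and 13995 in WT against 293A wt. The highest other split called 1 gene against USP7 KO#41 and 0 in the rest.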
